A study of Mus musculus with 10 samples.

How the data were processed

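RNA was measured by bulk sequencing in haematopoietic stem cells of mouse bone marrow. About 5000 cells per sample were sorted by flow cytometry as lineage-negative, Sca-1 positive, c-Kit positive, CD48 negative and CD150 positive cells. Libraries were made with the Smart-Seq V4 kit, which copies and amplifies polyadenylated RNA from small inputs, and were sequenced on an Illumina HiSeq. The labels give 5 control samples and 5 samples with a knockout of Dhx16, a DEAH-box RNA helicase of the spliceosome. The sample titles call the controls Dhx16_fl, with the genotype label WT, and the knockouts Dhx16_CKO, names that point to a floxed gene and a conditional knockout. The labels do not say whether each sample came from a different animal, so every p-value measures only the spread between samples.

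The authors listed Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq and the mm10 build, without saying which tool made which values, and the strand setting was not stated. The deposited values came as a single file of 52097 genes with 10 library columns, 5 named WT and 5 named CKO, beside result columns of the authors. The unit of the deposited library columns was not named in the header and was taken as FPKM (fragments scaled to transcript length and library size). This was inferred because the values had 2 decimals, summed to 770789 to 966648 per library, and because the mean count per FPKM rose with transcript length (Spearman 0.796 across 8244 genes, which are not independent replicates). The deposited column of mean normalized counts is a signal that the authors made with DESeq2. The deposited log2 fold changes and their standard errors were also made by the authors with DESeq2, and their sign against the library columns gives knockout over control. The deposited test statistic is a score from the authors' Wald test. Each deposited p-value and adjusted p-value also came from the authors' DESeq2 run.

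The library columns matched the 2 groups by their names but carried other numbers than the sample titles, so each column was assigned to a group and not to a titled sample. No read counts per library were used here and the depth of each library is unknown. No interval or detection limit that needs counts is given. All 52097 gene identifiers matched GENCODE mouse release M21, which uses the same assembly as mm10, and 9841 genes were at 0 in all 10 libraries.

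The plan written before the data were examined named a count model first and, for a table of normalized values only, limma on log2 (FPKM + 1). The second was used. Genes with 10 FPKM or more in at least 5 libraries were kept (6913 genes), so a gene could pass through the 5 libraries of 1 group alone. FPKM values were used as deposited, without further scaling between libraries. The fit had the 2 genotypes and no covariate, with limma's trend and robust options, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Changes are given as knockout minus control on the log2 scale. Exact permutation tests (two-sided) over all 5 against 5 assignments, whose smallest possible p is 0.00794, were used for single measures per library, with Benjamini-Hochberg adjustment over the 32 measures of that family.

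There were 34 gene lists fixed before the data were examined: p53 targets, spliceosome components, SR proteins and hnRNPs, DEAD and DEAH box helicases, ribosomal proteins, ribosome biogenesis, DNA replication and S phase, G2 and mitosis, cyclin-dependent kinase inhibitors and quiescence, haematopoietic stem cell genes, multipotent progenitor and lymphoid priming, sort markers, erythroid markers, megakaryocyte and platelet markers, granulocyte markers, monocyte and macrophage markers, B lymphocyte markers, T and NK lymphocyte markers, mast cell, basophil and eosinophil markers, endothelial and stromal markers, interferon-stimulated genes, NF-kB and inflammatory genes, apoptosis regulators, ATF4 integrated stress response, endoplasmic reticulum unfolded protein response, heat shock and proteotoxic stress, immediate early genes, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, glycolysis, DNA damage response and repair, replication-dependent histone genes, cholesterol synthesis and globin genes. The 32 lists with 3 or more tested members were compared with all other tested genes by limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation, fry and an exact permutation test of each list's mean per library, relative to all tested genes, were run beside it. Scores of other cell types are means of log2 (FPKM + 1) over 6 bone matrix genes (Col1a1, Col1a2, Sparc, Bglap, Dcn, Lum), 6 granulocyte genes (S100a8, S100a9, Ngp, Ltf, Camp, Lcn2), 6 macrophage genes (C1qa, C1qb, C1qc, Mrc1, Adgre1, Cd163), 8 erythroid genes without globins (Klf1, Ermap, Rhd, Rhag, Car1, Blvrb, Hemgn, Fech) and 4 globin genes.

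Genes named in the text followed a rule written before the data were examined. They were Dhx16, then the 12 largest rises and 12 largest falls among called genes whose control and knockout libraries did not overlap, leaving out predicted genes and immunoglobulin or T cell receptor segments. Then came up to 4 members of each list with the smallest adjusted p, or 2 where none was called, and Trp53, Cdkn1a, Mki67, Kit, Ly6a, Slamf1, Cd48, Procr, Myc and Gpkow. A few genes that the rule names are not reported here. The report gives values for the first member and for some of the others of each list. The part of the rule that asked for a mean count per library size did not apply to these values. Genes named for the cell type scores and for groups of genes chosen after seeing the data fall outside the rule.

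Alternatives tried were pseudocounts of 0.5 and 5, no filter and filters of 1 and 20 FPKM, a fit without the robust option, library quality weights, thresholds of 0.01 and 0.1, a test against a fold of 1.5 (limma's treat), each library left out in turn, and 4 scalings. The scalings were median-of-ratios factors, upper-quartile factors, equal total FPKM, and a shift of the knockout libraries by 0.41, the median offset of the authors' log2 fold changes from the FPKM ratios. The fit was also repeated without the libraries with the highest bone matrix or granulocyte score in each group and with both scores as covariates. The filters of 1 and 20 FPKM, the scalings, the weights, treat, the fits on bone matrix and granulocyte scores, the exact test of list means and the cell type scores themselves were chosen after the data had been seen. Count-based fits were not run because they need counts.

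The pipeline was tested on simulated data with 5 and 5 libraries and 6731 genes. It recovered 33.0% of 94 genes simulated with a log2 change of 0.5 and 91.8% of 97 genes with a change of 1, and 4% of its calls were false. The simulated noise was independent between genes, only 191 of the tested genes were changed, and no scaling offset between the groups was included. The real libraries differ in these points, so the rates show that the pipeline runs correctly and do not give its error rates on the real data. The software was R 4.3.3 with limma 3.58.1, statmod 1.5.0 and version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.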

Results

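The data were gene expression values of sorted haematopoietic stem cells from 5 control and 5 Dhx16 knockout samples. Each library was a column of FPKM values, whose sums were 830877 ± 74029 in control and 915797 ± 32825 in knockout libraries (mean ± SD, n = 5 each, exact permutation p = 0.0397, adjusted p = 0.0577). Depth was unknown because no counts per library were used. Of all genes, 14377 ± 435 were at 1 FPKM or more in control and 13063 ± 414 in knockout libraries (exact permutation p = 0.00794, adjusted p = 0.0159). Pairs of control libraries correlated across genes at 0.963 to 0.973, pairs of knockout libraries at 0.969 to 0.979 and mixed pairs at 0.949 to 0.966 (Pearson, log2 scale, genes are not independent replicates). The labels name 1 comparison, knockout against control, which asks what the loss of Dhx16 does to the RNA of haematopoietic stem cells. All gene values in the text are mean FPKM ± SD with n = 5 in each group, and changes are log2 differences, knockout minus control.

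Dhx16 itself (ENSMUSG00000024422, mm10 chromosome 17, 35879819 to 35892670) was at 17.5 ± 3.81 FPKM in control and 9.49 ± 1.56 FPKM in knockout libraries. The change was -0.81 with a standard error of 0.16 (limma adjusted p = 0.000638, exact permutation p = 0.00794). Its 5 knockout libraries, at 7.1 to 10.88 FPKM, were all below its 5 control libraries, at 14.33 to 22.63 FPKM. In the authors' table its log2 fold change was -0.90. The change ranged from -0.43 to -0.94 over the alternative settings, with the smallest fall under the scaling to the authors' fold changes (adjusted p = 0.0309). Whether the gene's value covers the deleted part is not known, so the remaining signal does not give the share of intact transcript. It also does not give the share of cells that kept the gene, which was not tested.

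**Figure D1:**
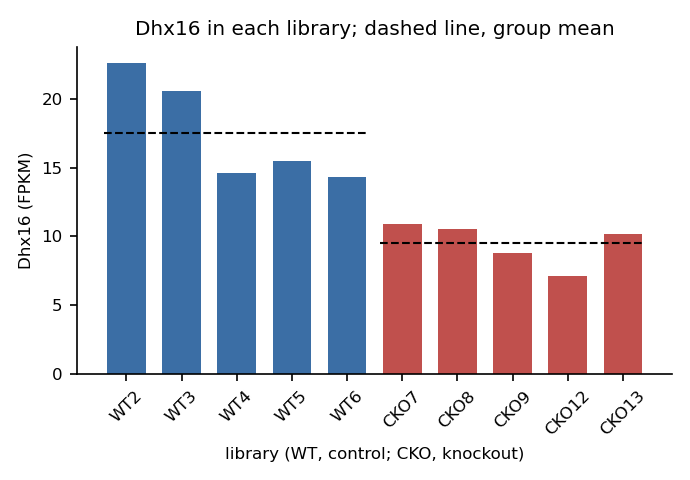
Dhx16 in each library (bars, FPKM; dashed lines, group means of 17.5 and 9.49). Each of the 5 knockout libraries was lower than each of the 5 control libraries.

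Of 6913 genes tested, 3642 were changed, 1460 higher and 2182 lower in knockout, and 4049 had an unadjusted p under 0.05. Of the changed genes, 3485 were protein-coding. The control and knockout libraries of 2402 changed genes did not overlap. Chance gives this for 0.794% of all genes, but the 2402 were counted among genes already called. The 2 rates are therefore not to be compared. Changes beyond 2-fold were seen in 269 genes that rose and 399 that fell. The balance between rises and falls depended on the scaling of the libraries. The share of called genes that were higher was 40.1% with the values as deposited, 39.6% with upper-quartile factors, 28.3% with equal totals, 78.9% with median-of-ratios factors and 79.7% with the scaling to the authors' fold changes. The median change of all tested genes was -0.12 with the values as deposited, -0.13, -0.25, 0.25 and 0.27 under those scalings in the same order, and list medians are to be read against it. Counts of list members called are likewise to be read against the 1460 higher and 2182 lower among all 6913 genes tested. Called in the same direction under all of these scalings were 1806 genes, 1055 higher and 751 lower, and 0 genes were called in opposite directions. The authors' table called 6698 of 23405 genes at an adjusted p under 0.05, of which 59.7% were higher, a wider set of genes than the 6913 tested here. Among the tested genes the authors called 3750. Of those, 1599 that were higher and 1 that was lower in the authors' table were not called here. Of the 3642 genes changed here, 2142 were called there with the same sign, 1492 were not called and 8 had the opposite sign.

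Of the 12 largest rises, 5 were on the list of erythroid markers (Mt2, Car1, Ermap, Rhd and Klf1). Sphk1 (chromosome 11, 116530925 to 116536674), the largest, rose from 6.77 ± 4.71 to 82.4 ± 17.2 FPKM (log2 3.61, adjusted p = 0.000108). Cldn13 rose from 14.7 ± 15.6 to 113 ± 23.5 FPKM, Car1 from 41.7 ± 38.9 to 288 ± 88.2, Ermap from 7.90 ± 6.73 to 65.4 ± 14.5, and Rhd from 12.7 ± 11.2 to 84.8 ± 14.5. The erythroid transcription factor gene Klf1 rose from 20.2 ± 12.1 to 111 ± 17.6 FPKM (log2 2.56, adjusted p = 0.000296). Add2, Slc38a5 and Tspo2 rose by log2 3.17, 2.98 and 2.59. The metallothionein genes Mt2 and Mt1, whose reads can be hard to tell apart, rose by log2 3.36 and 2.70. Cyclin E1 (Ccne1) rose from 8.85 ± 5.02 to 52.5 ± 9.16 FPKM. Of the 12 largest falls, 2 were on the list of megakaryocyte and platelet markers (Clec1b and Tubb1) and 3 on that of monocyte and macrophage markers. Clec1b (chromosome 6, 129397297 to 129409335) fell from 49.2 ± 18.0 to 2.62 ± 2.26 FPKM (log2 -3.90, adjusted p = 7.74e-05), Slc6a4 from 35.3 ± 14.0 to 1.85 ± 2.28, Tubb1 from 114 ± 50.6 to 7.73 ± 6.34, Alox12 from 23.7 ± 8.83 to 2.81 ± 1.60 and Tubb2a from 131 ± 41.7 to 21.4 ± 11.1. The complement genes C1qa, C1qb and C1qc fell by log2 -3.33, -3.33 and -3.30, and Fcna by -3.53. Ccl3 fell from 76.9 ± 9.84 to 10.9 ± 5.86 FPKM, Ston2 from 16.2 ± 4.84 to 1.39 ± 0.529 and Egr1 from 287 ± 50.1 to 56.3 ± 41.9 (log2 -2.66, adjusted p = 0.00267). All 24 of these genes held their direction and their call under the 4 other scalings.

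Of the 32 gene lists tested, camera called 18, 11 up and 7 down. With an estimated correlation camera called 0 lists (lowest adjusted p = 0.444) and 2 lists had an unadjusted p under 0.05. Fry, which tests whether the genes of a list move on balance in 1 direction, called 16 lists, and its mixed test called 29. Unlike camera, fry does not compare a list with the other genes. With 3642 of 6913 tested genes changed, many lists can pass it, above all the mixed test, so its calls do not show changes particular to a list. The exact permutation test of each list's mean per library, relative to all tested genes, passed for 22 lists (14 up and 8 down), 17 of them also called by camera. The other 5 were apoptosis regulators (exact permutation adjusted p = 0.0181) and T and NK lymphocyte markers (0.0462), both down, and SR proteins and hnRNPs (0.0181), DNA damage response and repair (0.0282) and replication-dependent histone genes (0.0462), all up. Of the 18 lists called by camera, the exact test missed the granulocyte markers, and fry missed these, the DEAD and DEAH box helicases and heat shock (adjusted p = 0.0663, 0.113 and 0.0928).

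**Figure D2:**
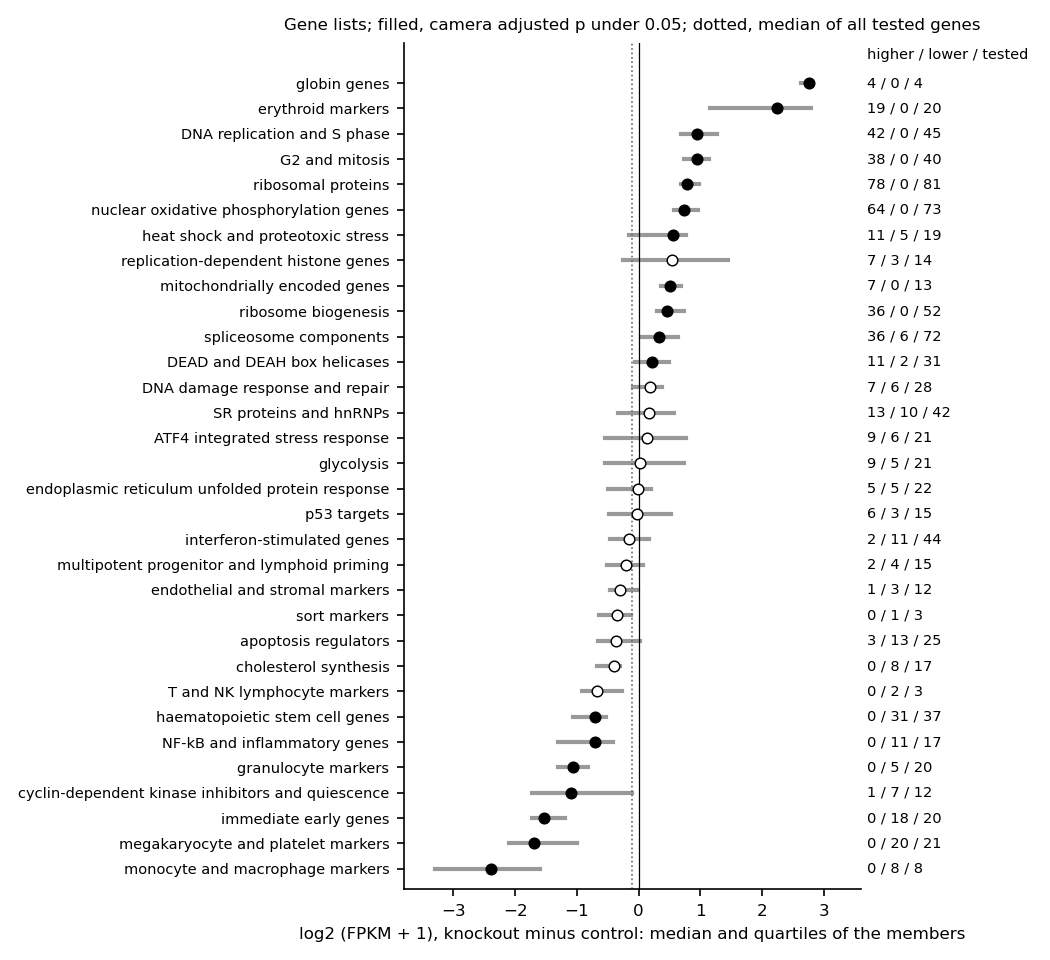
Median log2 change (points) and quartiles (grey bars) of the tested members of 32 gene lists, knockout minus control, filled where camera's adjusted p was under 0.05, the median of all tested genes dotted at -0.12, and members called higher, called lower and tested at the right. The globin list, the highest, has a median of 2.75 and the monocyte and macrophage list, the lowest, a median of -2.40.

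Genes of the cell cycle were higher in knockout. Of 45 DNA replication and S phase genes tested, 42 were higher and 0 lower (43 and 0 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 4.23e-18, and adjusted p = 0.459 with an estimated correlation). Mcm7 rose from 97.2 ± 9.75 to 257 ± 25.5 FPKM (log2 1.39, adjusted p = 1.7e-06), although its locus overlaps Cops6, Ap4m1 and Mir25. Rrm1 rose from 58.2 ± 11.3 to 186 ± 25.9 FPKM and Mcm5 from 68.5 ± 13.8 to 204 ± 21.2. Of 40 G2 and mitosis genes, 38 were higher and 0 lower (38 and 0 adjusted over the list alone), with a median of 0.94 (camera adjusted p = 5.77e-17, and adjusted p = 0.459 with an estimated correlation). Gtse1 rose from 5.23 ± 1.08 to 25.7 ± 6.92 FPKM, Ccna2 from 39.1 ± 7.30 to 113 ± 12.2, Ccnb1 from 39.7 ± 6.47 to 114 ± 16.5 and Plk1 from 24.4 ± 6.20 to 77.6 ± 11. Mki67 was below the filter, at 6.19 ± 1.26 and 8.98 ± 2.09 FPKM, and with a filter of 1 FPKM its change of 0.46 had an adjusted p of 0.05002, just above the threshold. Under every scaling 38 S phase genes and 35 G2 and mitosis genes stayed higher.

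Of 12 cyclin-dependent kinase inhibitors and quiescence genes tested, 7 were lower and 1 higher (the same 7 and 1 in number adjusted over the list alone), with a median of -1.09 (camera adjusted p = 0.0464, and adjusted p = 0.522 with an estimated correlation). That list's call was lost without any single library of WT2, WT3, WT5, WT6, CKO8 or CKO9 (adjusted p = 0.0519 to 0.0796), under the upper-quartile and equal-total scalings (0.0873 and 0.0652), without the libraries highest in bone matrix or granulocyte scores and with these scores as covariates (0.0774, 0.0813 and 0.123), while 6 of its genes stayed lower under every scaling. The list's median was -1.53 and -1.20 without the libraries highest in bone matrix and in granulocyte scores, and -0.94 with these scores as covariates. Cdkn2d fell from 85.0 ± 7.41 to 46.9 ± 7.57 FPKM, Klf6 from 246 ± 53.3 to 88.8 ± 39.3 and Btg1 from 41.0 ± 13.2 to 12.7 ± 4.70. The p53 target Cdkn1a was at 95.3 ± 22.3 and 98.0 ± 37.9 FPKM and was not called (adjusted p = 0.973). Of 14 replication-dependent histone genes tested, 7 were higher and 3 lower, as many as adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.299). The histone list was called without a filter and with a filter of 1 FPKM (camera adjusted p = 0.000318 and 0.0178). Hist1h2bc fell from 72.0 ± 7.38 to 23.8 ± 4.82 FPKM, Hist1h1c fell by 2.12 on the log2 scale and Hist1h2ab rose from 36.5 ± 18.2 to 103 ± 23.4 FPKM. Without the library CKO7, 4 histone genes were called higher in place of 7, and Smart-Seq libraries select polyadenylated RNA, which most of these transcripts lack.

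**Figure D3:**
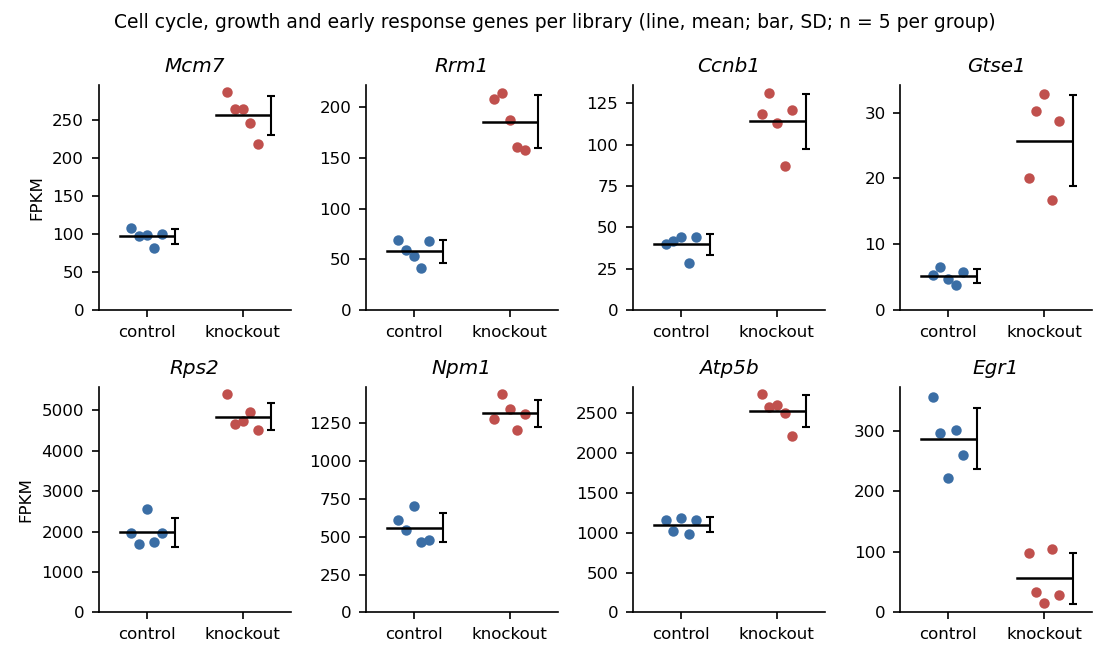
FPKM per library (points) of 8 cell cycle, growth and early response genes, with group means (lines) and SD (bars, n = 5). The 5 knockout libraries lay above all 5 control libraries for 7 genes, and below them for Egr1, at 15.82 to 104.4 against 221.78 to 355.74 FPKM.

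Ribosomal proteins and their assembly factors were higher in knockout. All 81 ribosomal protein genes were tested, and 78 were higher and 0 lower (80 and 0 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 3.36e-22, and adjusted p = 0.480 with an estimated correlation). Rps2 rose from 1982 ± 353 to 4851 ± 346 FPKM and Rpl29 from 536 ± 115 to 1231 ± 80.1, though many of these genes have processed pseudogenes that share their reads. Rps27l rose from 204 ± 75.9 to 581 ± 41.4 FPKM. Among 52 ribosome biogenesis genes 36 were higher and 0 lower, as many as adjusted over the list alone, with a median of 0.45 (camera adjusted p = 2.65e-11, and adjusted p = 0.480 with an estimated correlation). Imp4 rose from 49.0 ± 11.1 to 143 ± 14.8 FPKM, Npm1 from 561 ± 98.3 to 1317 ± 88.1 and Ncl, whose introns hold Snora75 and Mir3535, from 146 ± 33.5 to 321 ± 29.9. Under every scaling 77 ribosomal protein genes and 22 biogenesis genes stayed higher. Myc, which drives such genes in many cells, was at 234 ± 32.4 FPKM in control and 166 ± 48.8 in knockout (log2 -0.53, adjusted p = 0.0311). Its call was lost under the median-of-ratios and authors' scalings and without WT2, WT5, WT6, CKO8, CKO9 or CKO13 (adjusted p = 0.0786, 0.0759, 0.0509, 0.0596, 0.0543 and 0.0710). Without CKO13 its change was -0.35.

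Genes of mitochondrial respiration also rose. Of 73 nuclear oxidative phosphorylation genes, 64 were higher and 0 lower (67 and 0 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 6.61e-20, and adjusted p = 0.459 with an estimated correlation), and 59 stayed higher under every scaling. Cyc1 rose from 100.2 ± 15.2 to 235 ± 18.1 FPKM and Atp5b from 1102 ± 92.6 to 2527 ± 198. Of 13 mitochondrially encoded genes, 7 were higher and 0 lower, as many as adjusted over the list alone, with a median of 0.51 (camera adjusted p = 0.00188, and adjusted p = 0.607 with an estimated correlation). That number of 7 was 4 without WT2, 3 without WT3 and 11 without WT4, and mt-Nd1 rose from 2478 ± 796 to 4883 ± 249 FPKM and mt-Co1 from 5596 ± 894 to 8178 ± 501. Of 21 glycolysis genes 9 were higher and 5 lower, as many as adjusted over the list alone, with a median of 0.02 that changed sign between settings (camera adjusted p = 0.272). Gapdh rose from 1145 ± 129 to 2245 ± 290 FPKM and Bnip3 fell from 26.9 ± 4.11 to 12.7 ± 0.883. Among 17 cholesterol synthesis genes 8 were lower and 0 higher (7 and 0 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.0528), but only 2 stayed lower under every scaling and 5 were called without WT2 or without CKO13. The list as a whole was called without WT2, WT5, WT6, CKO8 or CKO9 (adjusted p = 0.0492, 0.0144, 0.00481, 0.0479 and 0.0394). It was also called under the median-of-ratios, upper-quartile and authors' scalings (camera adjusted p = 0.0196, 0.0384 and 0.0229), with medians of -0.04, -0.41 and -0.02. The same held without a filter and with bone matrix and granulocyte scores as covariates (camera adjusted p = 0.00502 and 0.0192). Insig1 fell from 30.1 ± 10.2 to 10.7 ± 1.49 FPKM.

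Splicing factors include the partners of Dhx16. Of 72 spliceosome components, 36 were higher and 6 lower (37 and 6 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 5.3e-07, and adjusted p = 0.522 with an estimated correlation). Under every scaling 29 stayed higher and 0 lower, and 3 were called lower without WT3 or without WT4. U2af1 rose from 86.6 ± 12.7 to 178 ± 15.6 FPKM, Snrnp40 from 65.5 ± 8.15 to 129.9 ± 9.20 and Ddx39b, which overlaps Gm22589, from 135 ± 21.4 to 288 ± 29.6. Gpkow, whose protein binds Dhx16, was at 13.9 ± 1.62 and 15.2 ± 2.76 FPKM (log2 0.11, adjusted p = 0.525), and was called higher under the median-of-ratios and authors' scalings. Of 42 SR proteins and hnRNPs, 13 were higher and 10 lower, as many as adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0734). Of these 42, 11 stayed higher and 4 lower under every scaling. That list was called without CKO9 or without CKO13 (adjusted p = 0.0283 and 0.0402), without a filter and with a filter of 1 FPKM (adjusted p = 8.40e-06 and 0.00191). Hnrnpa1 rose from 234 ± 22.8 to 533 ± 45.6 FPKM, while Luc7l2 fell from 46.7 ± 9.12 to 22.5 ± 2.01 and Srsf5 from 605 ± 47.4 to 313 ± 66.4, each in every scaling. Of 31 DEAD and DEAH box helicases, 11 were higher and 2 lower (9 and 2 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.0132, and adjusted p = 0.654 with an estimated correlation). Of these 31, 5 stayed higher and 1 lower under every scaling. The call of the helicase list was lost without WT4 and with a filter of 20 FPKM (adjusted p = 0.108 and 0.0777). Ddx1 rose from 32.5 ± 5.47 to 59.0 ± 6.07 FPKM and Ddx17 fell from 28 ± 6.51 to 14.5 ± 3.07. Splicing itself was not measured, since the values are per gene.

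Erythroid and megakaryocyte genes went in opposite directions. Of 20 erythroid markers, 19 were higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 2.24 (camera adjusted p = 1.96e-10, and adjusted p = 0.459 with an estimated correlation), and 18 stayed higher under every scaling. Epor rose from 18.2 ± 3.14 to 37.7 ± 2.01 FPKM, Blvrb from 68.9 ± 21.7 to 230.2 ± 39.3, Hemgn from 22.1 ± 6.13 to 49.1 ± 6.19 and Car2 from 1196 ± 221 to 2657 ± 452. All 4 globin genes were higher, also adjusted over the list alone, with a median of 2.75 (camera adjusted p = 0.0165, and adjusted p = 0.522 with an estimated correlation). Their libraries overlapped and varied widely, with Hba-a1 at 330.1 ± 429 in control and 1544 ± 926 FPKM in knockout and Hbb-bt at 190.1 ± 159 and 871 ± 503.7, and reads of their near-identical copies are shared. The list's call was lost under the median-of-ratios and authors' scalings and with library quality weights (adjusted p = 0.196, 0.146 and 0.0745). Its medians there were 3.14, 3.16 and 2.49. Without any of WT2, WT5, CKO7 or CKO12 only 2 of the 4 globin genes were called, with Hba-a1 at adjusted p = 0.0525, 0.0591, 0.0570 and 0.0515. Hbb-bs was also not called without WT3, CKO8 or CKO13 (adjusted p = 0.0546, 0.0546 and 0.0524), and 0 of the 4 were called without WT3 and CKO8 together. Of 21 megakaryocyte and platelet markers, 20 were lower and 0 higher, as many as adjusted over the list alone, with a median of -1.69 (camera adjusted p = 8.83e-09, and adjusted p = 0.444 with an estimated correlation), and 17 stayed lower under every scaling. Vwf fell from 43.0 ± 9.06 to 12.5 ± 1.95 FPKM, F2rl2 from 20.6 ± 2.87 to 4.61 ± 1.18, Itgb3 from 19.9 ± 6.30 to 3.69 ± 0.316 and Treml1 from 44.9 ± 6.11 to 7.39 ± 3.77.

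**Figure D4:**
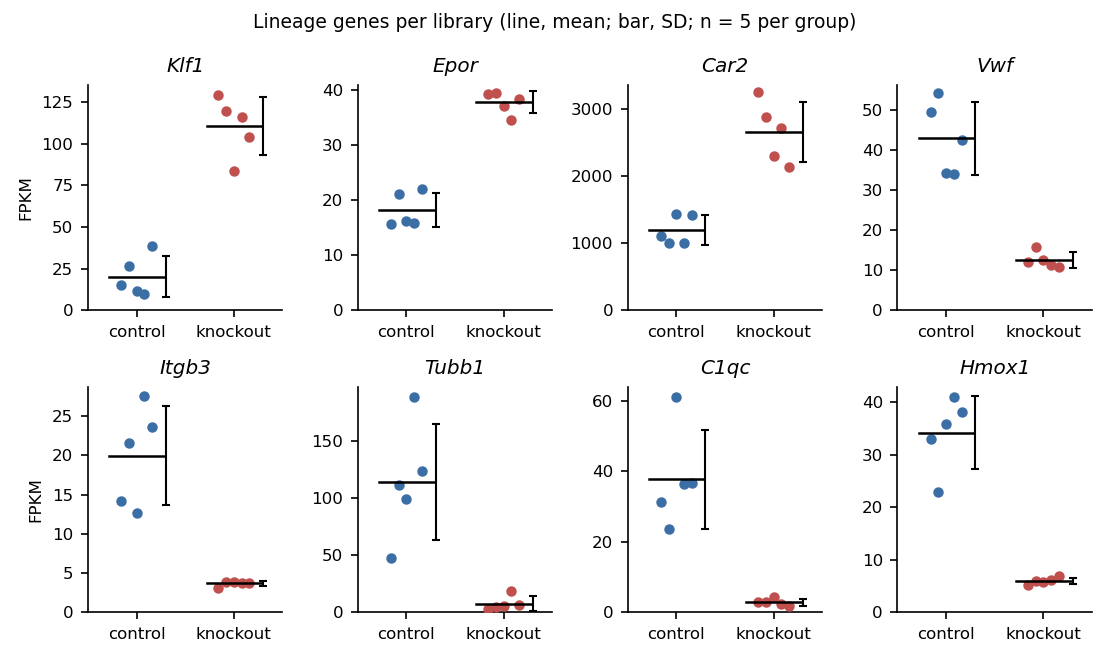
FPKM per library (points) of 8 lineage genes, with group means (lines) and SD (bars, n = 5). The 5 knockout libraries lay above all 5 control libraries for Klf1, Epor and Car2, and below them for Vwf, Itgb3, Tubb1, C1qc and Hmox1, which fell to 5.3 to 6.91 FPKM from 22.87 to 40.92.

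Genes typical of haematopoietic stem cells were lower. Of 37 tested, 31 were lower and 0 higher (33 lower and 1 higher adjusted over the list alone), with a median of -0.70 (camera adjusted p = 1.2e-06, and adjusted p = 0.459 with an estimated correlation). That number fell to 16 under the median-of-ratios scaling, and 15 stayed lower under every scaling. Runx1 fell from 50.2 ± 10.4 to 20.7 ± 2.33 FPKM, Ltb from 96.9 ± 6.73 to 41.5 ± 6.85 and Cd9 from 272 ± 25.9 to 142 ± 18.1. Procr fell from 41.2 ± 9.36 to 26.2 ± 5.74 FPKM (log2 -0.63, adjusted p = 0.00466), but was not called under the median-of-ratios and authors' scalings. Of the genes of the surface proteins used for the sort, 3 were tested and 1 was lower, also adjusted over the list alone, with a median of -0.36 that changed sign between scalings (camera adjusted p = 0.489). Slamf1, which encodes CD150, fell from 21.5 ± 4.65 to 10.9 ± 2.20 FPKM (log2 -0.92, adjusted p = 0.000277). Kit was at 154 ± 26.1 and 123 ± 37.0 FPKM (adjusted p = 0.144) and Ly6a at 196 ± 77.5 and 203 ± 36.4 (adjusted p = 0.692). Cd48 was below the filter at 10.3 ± 3.99 and 6.86 ± 1.09 FPKM (log2 -0.46, adjusted p = 0.0827 with a filter of 1 FPKM). Of 15 multipotent progenitor and lymphoid priming genes 2 were higher and 4 lower, as many as adjusted over the list alone, with a median of -0.21 that changed sign between scalings (camera adjusted p = 0.489). Il12a rose from 32.5 ± 9.48 to 126 ± 16.9 FPKM and Ighm fell from 18.4 ± 4.54 to 6.06 ± 1.76.

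Early response and inflammatory genes were lower in knockout. Among 20 immediate early genes 18 were lower and 0 higher (19 and 0 adjusted over the list alone), with a median of -1.53 (camera adjusted p = 8.28e-05, and adjusted p = 0.598 with an estimated correlation), and 10 stayed lower under every scaling. Fosb fell from 79.7 ± 23.4 to 23.4 ± 6.33 FPKM and Dusp2 from 593 ± 70.3 to 225 ± 106. For NF-kB and inflammatory genes, 11 of 17 were lower and 0 higher (12 and 0 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 0.00601, and adjusted p = 0.459 with an estimated correlation), and 6 stayed lower under every scaling. Zfp36 fell from 428 ± 108 to 144 ± 51.3 FPKM, Traf1 from 13.4 ± 2.61 to 5.65 ± 0.902 and Birc3 from 22.1 ± 3.98 to 11.7 ± 1.52. Of 44 interferon-stimulated genes 2 were higher and 11 lower (2 and 8 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.572). Those numbers turned to 15 higher and 2 lower under the median-of-ratios scaling, and without WT2, CKO12 or CKO13 the list changed to 6 lower, 5 higher or 7 lower. Sp100 fell from 61.7 ± 7.65 to 34.0 ± 4.37 FPKM and Isg20 rose from 45.7 ± 8.99 to 72.5 ± 5.82.

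Stress and damage pathways were mixed, and their balance depended on the scaling. Counts of called members alone do not single out a list, as 3642 of all 6913 tested genes were changed. Trp53 rose from 200.5 ± 22.0 to 396 ± 39.2 FPKM (log2 0.98, adjusted p = 2.08e-05). Of 15 p53 targets, 6 were higher and 3 lower (6 and 4 adjusted over the list alone), with a median of -0.03, a mean of 0.00 and an upward camera test (adjusted p = 0.397). The higher targets numbered 3 without CKO8, and the lower ones 5 without CKO9 or CKO12. Bax rose from 69.6 ± 9.19 to 137 ± 16.1 FPKM, Psrc1 from 13.0 ± 1.90 to 50.1 ± 13.8 and Pidd1 from 7.45 ± 1.30 to 15.3 ± 2.81. Of 28 DNA damage response and repair genes 7 were higher and 6 lower, as many as adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.111). Without WT5 or without CKO8 the higher ones numbered 4, and under the median-of-ratios scaling 20. That list was called without a filter and with a filter of 1 FPKM (camera adjusted p = 1.32e-07 and 0.000353). Trp53bp1 fell from 22.9 ± 2.57 to 13.4 ± 1.24 FPKM. Of 21 genes of the ATF4 integrated stress response 9 were higher and 6 lower, as many as adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.106). Of the 21, 8 stayed higher and 2 lower under every scaling. Asns rose from 23.6 ± 7.23 to 75.5 ± 13.3 FPKM while Ddit3 fell from 78.8 ± 9.65 to 29.7 ± 7.13. In the endoplasmic reticulum unfolded protein response 5 of 22 genes were higher and 5 lower, as many as adjusted over the list alone, with a median of -0.01 (camera adjusted p = 0.948), and 3 were higher without WT5 or without WT6. Dnajb9 fell from 60.7 ± 6.10 to 22.4 ± 5.67 FPKM and Herpud1 from 117 ± 8.46 to 61.8 ± 8.11.

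Of 19 heat shock and proteotoxic stress genes, 11 were higher and 5 lower, as many as adjusted over the list alone, with a median of 0.55 (camera adjusted p = 0.0338, and adjusted p = 0.623 with an estimated correlation). That call was lost under the median-of-ratios and authors' scalings and with a filter of 20 FPKM (adjusted p = 0.138, 0.146 and 0.0883), and without WT2, WT3 or WT5 the lower genes numbered 3. Hspd1 rose from 143 ± 21.5 to 360.3 ± 47.1 FPKM and its neighbour Hspe1 from 96.8 ± 25.5 to 245 ± 27.98, while Dnajb4 fell from 34.8 ± 3.21 to 13.6 ± 2.75. Among 25 apoptosis regulators 3 were higher and 13 lower, as many as adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.112, adjusted p = 0.00970 with fry and 0.0181 in the exact permutation test), and 3 and 5 held under every scaling. Birc2 fell from 40.2 ± 3.90 to 21.7 ± 1.49 FPKM and Cycs rose from 57.1 ± 14.8 to 128 ± 15.4.

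Markers of mature myeloid and other cells were examined because the sort should exclude those cells. All 8 monocyte and macrophage markers tested were lower, also adjusted over the list alone, with a median of -2.40 (camera adjusted p = 1.92e-05, and adjusted p = 0.444 with an estimated correlation), and 7 stayed lower under every scaling. Hmox1 fell from 34.1 ± 6.96 to 6.03 ± 0.582 FPKM, Axl from 13.6 ± 2.75 to 3.33 ± 0.822 and Vcam1 from 40.9 ± 12.7 to 6.4 ± 2.30. When any of the 5 control libraries was left out only 3 of these markers passed the filter, and 3 were called lower without WT4 and 2 without WT2, WT3, WT5 or WT6. Of 20 granulocyte markers 5 were lower and 0 higher (1 and 0 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 0.0290, adjusted p = 0.654 with an estimated correlation, 0.0663 with fry and 0.117 in the exact permutation test). None of these 5 stayed called under every scaling, and the list's call was lost without WT3 or without CKO9 (adjusted p = 0.0603 and 0.104), with a filter of 1 FPKM (0.0673), under the upper-quartile and equal-total scalings (0.0633 and 0.0652) and with bone matrix and granulocyte scores as covariates (0.517). Without WT2 the lower markers numbered 8, without WT4 3, and without WT3, WT5, CKO7, CKO9, CKO12 or CKO13 2. Padi4 fell from 63.8 ± 19.8 to 33.2 ± 6.92 FPKM and Prtn3 from 295 ± 69.9 to 153 ± 75. The B lymphocyte markers Cd79b and Cd72 were the only 2 tested and both were lower, also adjusted over the list alone, at 34.9 ± 7.76 and 22.5 ± 5.15 FPKM for Cd79b. Of 3 T and NK lymphocyte markers 2 were lower, also adjusted over the list alone, with a median of -0.68 (camera adjusted p = 0.455), and Lat fell from 77.6 ± 14.3 to 48.1 ± 8.95 FPKM. No B, T or NK call held under every scaling. Of mast cell, basophil and eosinophil markers 2 were tested and 0 called, also adjusted over the list alone, Hdc at 23.5 ± 16.3 and 12.4 ± 6.34 FPKM (adjusted p = 0.250) and Prg2 at 18.1 ± 23.6 and 75.2 ± 99.96 (adjusted p = 0.587). Of 12 endothelial and stromal markers 1 was higher and 3 lower (1 and 2 adjusted over the list alone), with a median of -0.30 that changed sign between scalings (camera adjusted p = 0.647). Pecam1 fell from 36.7 ± 6.59 to 14.3 ± 2.50 FPKM and Egfl7 rose from 110.4 ± 22.1 to 178 ± 29.8.

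Transcripts of bone matrix and granulocytes were abundant in all 10 libraries. Bglap averaged 12828 FPKM in control (1282 to 40600) and 11507 in knockout (2270 to 28559), and S100a8 averaged 18892 and 11418. The bone matrix score was 9.49 ± 1.47 in control and 9.38 ± 1.33 in knockout (exact permutation p = 0.905, adjusted p = 0.929), and the granulocyte score 11.3 ± 1.22 and 10.2 ± 0.868 (exact permutation p = 0.127, adjusted p = 0.163). The macrophage score was lower in all 5 knockout libraries, at 4.07 ± 0.284 against 1.57 ± 0.271 (exact permutation p = 0.00794, adjusted p = 0.0159). The erythroid score without globins was higher in all 5, at 4.30 ± 0.780 against 6.57 ± 0.210 (exact permutation p = 0.00794, adjusted p = 0.0159), and the globin score was 7.11 ± 1.44 against 9.77 ± 1.01 (exact permutation p = 0.0159, adjusted p = 0.0282). Without the libraries with the highest bone matrix score (WT6 and CKO13) 2695 genes were changed, and 2668 of the 3352 calls still tested were kept. Without those with the highest granulocyte score (WT3 and CKO8) 2716 were changed, and 2687 of 3347 were kept.

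**Figure D5:**
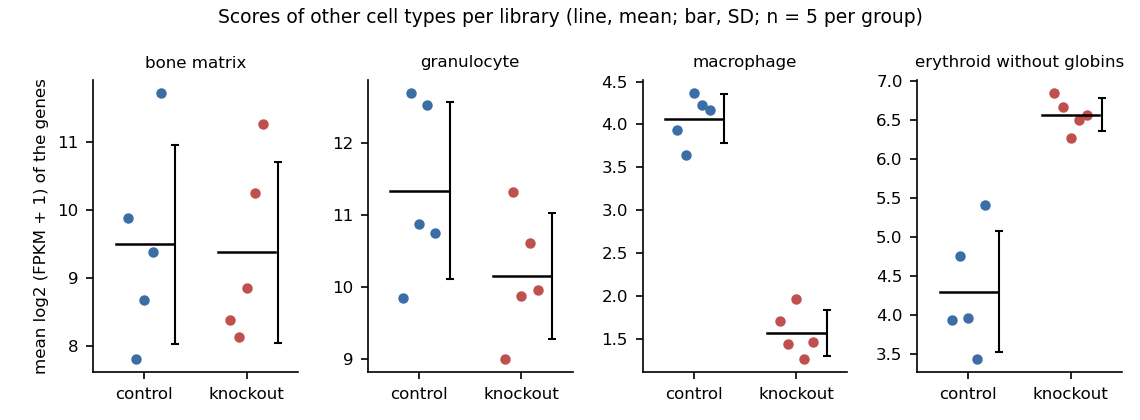
Mean log2 (FPKM + 1) of the genes of 4 cell types per library (points), with group means (lines) and SD (bars, n = 5). Bone matrix and granulocyte scores of the groups overlapped, while the macrophage score was lower in every knockout library (1.57 ± 0.271) than in every control library (4.07 ± 0.284) and the erythroid score was higher.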

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

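The tests on other blood cell types and the test of depth for lincRNA genes were chosen only after the results they bear on had been seen, while those on splits, scaling, length, GC content and single-exon genes were written before, although the 4 scalings themselves were chosen after the data had been seen.

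The 5 values of each group were examined for each of 148 named genes. In 20 of 296 groups (6.76%) the highest or lowest library lay apart from the other 4, by a gap of more than 0.71 of the group's whole range on the log2 scale (Dixon's 95% critical value), and chance gives about 1 in 20. Among the control libraries, WT4 stood highest for Rps27l (339.1 FPKM, the others 157.68 to 176.74) and Xpa (32.04, the others 20.42 to 22.38), and lowest for Hist1h1c (64.74, the others 122.93 to 141.54). The control library WT5 stood lowest for Psrc1 (9.7 FPKM, the others 13.09 to 14.44), Ccnb1 (28.59, the others 39.84 to 44.34) and Isg20 (30.27, the others 46.1 to 52.97). The control library WT3 stood highest for Ncl (205.32 FPKM, the others 124.12 to 137.9) and lowest for Ccl5 (7.18, the others 11.15 to 13.22). WT2 stood highest for Xbp1 (131.09 FPKM, the others 98.32 to 103.16), and WT6 stood lowest for Sp100 (48.18, the others 63.08 to 66.14).

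Among the knockout libraries, CKO12 stood lowest for Sphk1 (52.55 FPKM, the others 82.79 to 92.59) and highest for Slc6a4 (5.91, the others 0.62 to 1.21) and Treml1 (14.06, the others 4.88 to 6.41). CKO9 stood highest for Slamf1 (14.71 FPKM, the others 9.4 to 10.46) and lowest for Fosb (12.46, the others 24.5 to 27.96). CKO13 stood lowest for Lat (33.46 FPKM, the others 47.94 to 55.38), mt-Cytb (4432.71, the others 5266.44 to 5567.36) and Srebf2 (45.01, the others 61.82 to 69.97). CKO7 stood lowest for Itgb3 (3.14 FPKM, the others 3.74 to 3.92) and CKO8 highest for Ly6c2 (97.01, the others 38.09 to 40.12). No explanation of these single values was tested.

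The 3642 changed genes were set against 100 splits of the 10 libraries into 5 and 5, drawn from the 126 possible. Only 1 of the 100, the real one, gave as many, and the highest of the others gave 4 genes, which argues against an arbitrary split as the source of that count. The other splits mix both genotypes in each group, so the genotype difference adds to their spread and lowers their counts. A difference in handling that follows the genotype would give the same result and was not tested. For the 18 gene lists called by camera, 16 of the 100 splits gave as many, and the highest of the others gave 20 lists. Chance cannot be excluded for the number of lists called. The exact test of list means per library, which passed for 22 lists, was added after this was seen.

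Ribosomal protein and nuclear oxidative phosphorylation genes were higher in knockout. At least 136 of the 154 members were called higher under each of the 4 scalings, which argues against scaling as the cause within the range of these 4. Of them, equal totals lowered the median change of all tested genes the most, from -0.12 to -0.25, and a larger shift in that direction was not tried. A bias by transcript length, GC content and expression level could contribute to the rise, and the trend fitted on them did not account for all of it. After the trend of 6759 other genes was removed (R squared 0.0937), the members' median change was 0.52 (95% bootstrap interval over genes 0.460 to 0.584), against 0.785 before. These genes are not independent replicates, so the interval does not measure the spread between libraries, and a bias that the trend misses is not excluded. With bone matrix and granulocyte scores as covariates 63 of the 81 ribosomal protein genes and 48 of the 73 oxidative phosphorylation genes were still called higher. Reads shared with pseudogenes of ribosomal proteins, a different mix of stem and progenitor cells in the gate and an effect of the genotype within cells stay open and were not tested.

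Markers of other blood cell types changed in knockout, with macrophage genes lower and erythroid genes higher. A lower share of every contaminating cell type to the same degree is argued against. The macrophage score minus the mean of the granulocyte and bone matrix scores fell by 1.85 in knockout (exact permutation p = 0.0159, two-sided). Falls of unequal size are not excluded, with differences of -2.50 for the macrophage, -1.19 for the granulocyte and -0.12 for the bone matrix score. The macrophage score was chosen after the data had been seen, so its fall is no separate support. Fewer macrophages or macrophage fragments among the sorted cells cannot be told apart from lower expression within the cells. The 86.4% of 22 macrophage list members at 1 FPKM or more in control that were lower only restates the pattern. The sort for Sca-1 and c-Kit and against lineage markers should remove mature macrophages. Granulocyte transcripts were abundant in control despite that sort (S100a8 at 18892 FPKM), so it does not weigh against carried-over RNA. Neither does the level of C1qb, the most abundant list member, at 76.3 FPKM in control. Haemoglobin-rich red cells as the source of the other erythroid genes stay open too, as the 2 groups gave different answers: the erythroid score without globins spanned 0.571 against 2.72 for the globin score within knockout (ratio 0.210), but 1.97 against 3.77 within control (ratio 0.524). The sort should remove red cells too, with the same limit as for macrophages. Erythroid progenitors within the gate and a change within the stem cells themselves also stay open, as untested.

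LincRNA genes took 1.06% ± 0.324 of total FPKM in control and 0.438% ± 0.0770 in knockout libraries (SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0159). Whether the knockout libraries had lower depth is unknown, and the test set for this explanation did not exclude it. Among genes with a mean count of 200 or more, the median difference of 29 lincRNA genes from protein-coding genes of the same mean count was -0.388 in the authors' log2 fold changes, with an interval of -0.799 to -0.0988 whose upper end missed the bound of -0.1 set for the test. Both ends of that interval were negative, so these lincRNA genes were still lower than matched genes at these counts. More genomic DNA or unspliced RNA in the control libraries cannot be told apart from a fall of spliced transcripts. Single-exon lincRNA and TEC genes differed from multi-exon lincRNA genes by a median of 0.0227 (interval -0.235 to 0.198, 137 and 81 genes), which is too wide to decide.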

How the results depend on the processing

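The filters of 1 and 20 FPKM, the 4 scalings, library quality weights, treat, the fits on bone matrix and granulocyte scores and the exact test of list means were chosen after seeing the data. The pseudocounts, no filter, the fit without the robust option, the thresholds, each library left out, the estimated correlation and fry were set before.

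The number of changed genes, 3642, rose to 5910 without a filter (4523 lower) and to 6687 with a filter of 1 FPKM (4890 lower), because more genes were tested, and 2804 and 3582 of the 3642 calls were kept. With a filter of 20 FPKM 1263 genes were lower, because fewer genes were tested. Treat, which asks for more than a 1.5-fold change, called 450 genes, 180 higher and 270 lower. The 1460 genes higher and 2182 lower became 3053 and 816 under median-of-ratios scaling and 3041 and 776 under the scaling to the authors' fold changes, because these scalings raise every gene of the knockout libraries relative to control. With bone matrix and granulocyte scores as covariates 954 genes were higher, and 2849 of the 3642 calls were kept. The cause was not tested. Under the pseudocounts, the fit without the robust option, the upper-quartile and equal-total scalings, the weights and the thresholds of 0.01 and 0.1 the numbers of changed, higher and lower genes stayed within 1.5 times the reported ones.

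Leaving out 1 library at a time gave 2974 (without WT5) to 3529 (without CKO12) changed genes, 1231 to 1597 higher and 1655 to 2227 lower, 16 to 19 called lists and a change of Dhx16 of -0.87 to -0.72. Dhx16 stayed lower with an adjusted p of at most 0.0309 under every alternative in which it was tested. It was below the filter of 20 FPKM and has no value there.

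The 18 lists called by camera became 0 with an estimated correlation, the only setting that differed between these 2 runs. The estimates for the 18 lists ran from 0.139 (NF-kB and inflammatory genes) to 0.962 (globin genes), all far above the preset 0.01. For ribosomal proteins the estimate was 0.862. The p-values with the preset correlation therefore rest on a value well below these estimates. Of the 18, 13 were kept under every other alternative with camera, and 5 were lost under some of them. These 5 were the DEAD and DEAH box helicases, the cyclin-dependent kinase inhibitors, the granulocyte markers, heat shock and globin genes. Gained under some alternative were 8 lists. Of the 147 named genes besides Dhx16, 141 were called, 116 of them under every alternative. The other 25 were lost under some alternative, 19 of them under a scaling, 13 without the libraries high in bone matrix or granulocyte scores or with these as covariates, and 7 without 1 library. Gpkow was gained under 2 scalings. None of these 147 genes and no list, where called in the reported fit, took the opposite direction under an alternative, but some of these genes and the medians of some lists that were not called there changed sign, and the balance of higher and lower genes turned over under 2 scalings.

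No paired analysis was possible because the library columns (WT2 to WT6 and CKO7 to CKO13) could not be matched to the titled samples. Fits that need counts (DESeq2, edgeR, voom, glmTreat, their normalizations and filters in counts) were not run. What depth limits cannot be given in counts, since the depth is unknown.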

Other observations

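All tests in this part were chosen only after the data had been seen. They concern shares of RNA classes and 9 groups of genes other than the lists fixed beforehand, though some groups share single genes with them, the groups picked because single members stood out, so that the group tests restate what was noticed and are no independent evidence.

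All 8 CCT chaperonin subunits were higher in knockout (median log2 0.88, camera adjusted p = 4.63e-07, and 0.219 with an estimated correlation). Cct8 rose from 169 ± 19.9 to 385 ± 36.5 FPKM (SD, n = 5). Of 31 proteasome subunits 30 were higher and 0 lower (median 0.80, camera adjusted p = 1.24e-14, and 0.219 with an estimated correlation), with Psmc6 rising from 51.1 ± 6.002 to 125 ± 5.73 FPKM. Among 31 translation initiation and elongation factors 23 were higher and 1 lower (median 0.59, camera adjusted p = 2.02e-09, and 0.219 with an estimated correlation), with Eif5a rising from 1255 ± 158 to 2692 ± 172 FPKM and Eif4a2 falling from 298 ± 31.4 to 194 ± 18.7. Of 20 aminoacyl-tRNA synthetases 16 were higher and 0 lower (median 0.58, camera adjusted p = 1.48e-08, and 0.219 with an estimated correlation). Hars rose from 51.2 ± 7.86 to 120.1 ± 9.52 FPKM.

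Of 72 mitochondrial ribosomal proteins 44 were higher and 0 lower (median 0.44, camera adjusted p = 1.32e-10, and 0.272 with an estimated correlation). Of 26 mitochondrial import genes 20 were higher and 2 lower (median 0.67, camera adjusted p = 7.56e-08, and 0.227 with an estimated correlation), with Phb2 rising from 139 ± 14.97 to 367 ± 29.6 FPKM. Of 9 haem synthesis genes 6 were higher and 0 lower (median 0.84, camera adjusted p = 0.00333, and 0.227 with an estimated correlation), with Alad rising from 87.1 ± 19.3 to 222 ± 34.0 FPKM.

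Tubulin genes split. Of 10 tested, 6 were higher and 3 lower (median 0.77, camera adjusted p = 0.0389, and 0.272 with an estimated correlation). Tuba1b rose from 943 ± 176 to 3075 ± 442 FPKM, while Tubb1, Tubb2a and Tuba8 fell by 3.83, 2.60 and 1.14 on the log2 scale. Of 22 polycomb and chromatin-modifying enzymes 4 were higher and 11 lower (median -0.42, camera adjusted p = 0.0535, and 0.445 with an estimated correlation). Cbx7 fell from 17.4 ± 2.87 to 6.76 ± 1.70 FPKM and Ezh1 from 18.1 ± 2.76 to 8.92 ± 0.938. These values are with the libraries scaled as deposited, and the other scalings were not applied to these groups.

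TEC genes took 0.758% ± 0.134 of total FPKM in control and 0.339% ± 0.0326 in knockout libraries, antisense RNA genes 0.213% ± 0.0190 and 0.165% ± 0.0160 and sense intronic genes 0.0238% ± 0.00127 and 0.0142% ± 0.00260 (SD, n = 5, exact permutation p = 0.00794 and adjusted p = 0.0159 for each). Mitochondrially encoded genes took 4.95% ± 0.766 and 6.18% ± 0.307 (exact permutation p = 0.0317, adjusted p = 0.0508). The most abundant gene, CT010467.1, took 7.77% ± 1.60 in control and 6.02% ± 1.24 in knockout libraries (exact permutation p = 0.0873, adjusted p = 0.116). It made up nearly all of the ribosomal RNA class, which took 7.78% in control and 6.02% in knockout libraries. Ptprc, which encodes the pan-leukocyte protein CD45, was at 90.0 ± 12.4 and 52.5 ± 8.59 FPKM (exact permutation p = 0.00794, adjusted p = 0.0159).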
